A study of Mus musculus with 119 samples.

How the data were processed

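The authors deposited a scanner output file for each of the 119 arrays and a table of processed values. Per the file headers, Agilent Feature Extraction 9.1.3.1 read the intensity of each spot and of its local background in both channels, and also subtracted background, removed spatial trends and normalised the dyes in its processed columns. The deposited log10 ratio of Cy5 over Cy3 comes from those processed signals, per the file headers, and was exactly 0 at 23.5% to 30.1% of spots per array with 1 array per slide and at 18.5% to 28.8% with 4 arrays per slide. The authors' table was read as log2 ratios, because its columns correlated with the software's log10 ratio of the same array at r = 0.941 to 0.968 (slope 2.22 to 2.50) and r = 0.976 to 0.994 (slope 2.62 to 3.03) on the respective designs. Its column medians ran from -0.04 to 0.02 and from -0.05 to 0.08, it holds 16515 probes, and its normalisation, filter and any centring are unknown. Per the labels' protocols, RNA of low integrity was discarded and the reference was a pool of wild type whole brain RNA in Cy3. The dyes were never swapped, as Cy5 always held the sample, so a dye bias of a probe is shared by both genotypes and drops out of their difference. The labels give as many mice as arrays (60 AD11 and 59 VH).

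The 2 array designs were fitted apart. The design with 1 array per slide had 50 arrays of 43790 spots, 2256 of them control spots, on 50 slides and 5 scan days, and that with 4 arrays per slide had 69 arrays of 45018 spots, 1639 of them control spots, on 18 slides and 4 scan days. The percentage of probes well above background in Cy3 ran from 55.6% to 64.0% and from 62.4% to 72.6%. Spot intensity was corrected for background with normexp (offset 50) on all spots and normalised within each array by loess with control and outlier spots at weight 0, in limma 3.58.1 on R 4.3.3 with statmod 1.5.0 and the data.table package (1.17.8). Control spots and spots that the software marked as outliers were then left out, saturated spots were kept, and spots of the same probe were averaged. A probe was kept when well above background in Cy5 in at least 4 arrays of any group, which left 27075 and 28407 of 41174 probes.

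Names came first from the accession and then from the symbol or a synonym in a reference annotation (assembly GRCm38.p6), which was used only for names and for the order of genes. With 1 array per slide 22864 probes were named by accession, 6732 by a current symbol and 3498 by a synonym, 2076 kept the name in the file and 6004 stayed unnamed. With 4 arrays per slide the numbers were 22951, 6659, 3109, 1881 and 6574. Of several kept probes of a gene, the probe with the highest mean log2 intensity of both channels over all arrays stood for it (6230 and 6555 genes had several), which gave 18258 features with 15721 named genes and 19049 with 15984. Features are named genes or unnamed probes.

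The limma model held a mean for each age, area and genotype, with eBayes moderation (residual df 40 and 55, prior df 3.52 and 3.61) and Benjamini-Hochberg adjustment over all features, and an adjusted p under 0.05 passed. The tests were two-sided, and ± in a gene value is the model's standard error. The design, the gene lists, the named genes and most alternatives were fixed before the data were examined. There were 12 comparisons of AD11 with VH, 4 means over areas, 6 interactions with age and 6 age comparisons in VH, 28 in all. Named genes are the 4 that passed with the largest rise and fall and no overlap between groups in each comparison, 10 for a mean over areas, 3 for interactions and age, up to 4 of a gene list, the genes about which the study turns, and the genes that passed alike in at least 6 of 12 comparisons.

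Gene lists, 39 in all, were written from general knowledge, and 608 list tests used camera with a preset correlation of 0.01 for lists with at least 3 measured genes. Camera sets a list against all other genes, while fry asks whether its genes move on balance in 1 direction. No call of the 126 held with an estimated correlation, and in all of them median, mean and test had the same sign.

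A fold given as at least a value has 1 group in which a probe was not well above background on any array. The bright group's mean was set against the dim group's mean, in which each array counted with the higher of its lowest well above background signal and the probe's own. These are Cy5 values after loess and Aquantile normalisation, and they are open to dye bias. With n = 5 and 5, a gene with no effect has no overlap between groups in 0.794% of cases.

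The slide and the scan day were tested as batches. The slide's consensus correlation was 0.132 on the design with 4 arrays per slide. Both genotypes of a comparison shared a scan day except in hippocampus at 1 month, and 1 AD11 cortex array at 1 month and 1 VH basal forebrain array at 6 months were scanned on a further day. On simulated values, run first, 200 features were changed by a log2 value of 0.5, 1 or 2. In basal forebrain at 1 month 76.1%, 97.0% and 100% were found, with 12 false calls. In cortex at 3 months 88.1%, 97.0% and 100% were found, with 20 false calls. Real arrays may differ: grouped otherwise, those of the former gave up to 1954 features.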

Results

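The series measured RNA levels in brain tissue of female AD11 mice, a transgenic line that makes an antibody against nerve growth factor (NGF), and of female VH mice, a transgenic control line that carries only the heavy chain of that antibody. Basal forebrain, cortex and hippocampus of the right hemisphere were sampled at 1, 3, 6 and 15 months of age, which gave 24 groups and 119 arrays. Each group held 5 arrays except VH basal forebrain at 6 months, which held 4. The sample was labelled with Cy5 and hybridised with a Cy3-labelled pool of wild-type whole brain. On the 50 arrays of the design with 1 array per slide the share of probes well above background in Cy5 ran from 56.3% to 67.1%, and on the 69 arrays of the design with 4 arrays per slide from 57.1% to 70.5%. The number of arrays limits the precision. The labels give as many mice as arrays in each genotype, and they do not link arrays of different areas to the same animal. All differences below are log2 values of AD11 minus VH with the standard error of the model (n = 5 and 5 unless stated), and a gene rose or fell where its adjusted p was under 0.05.

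The first question was whether AD11 mice had altered messages of NGF, its receptors and the cholinergic neurons that depend on it. Ngf itself did not pass in any of the 12 comparisons, with differences from -0.15 ± 0.08 in cortex at 3 months (-0.024 without AD11 replicate 2) to 0.11 ± 0.11 in hippocampus at 15 months (0.057 without VH replicate 5). Ntrk1, which encodes the NGF receptor TrkA, fell in basal forebrain at 1 month (-1.22 ± 0.31, adjusted p = 0.0227), and Ache, the enzyme that breaks down acetylcholine, fell there as well (-0.69 ± 0.16, adjusted p = 0.00824). Ngfr, the p75 neurotrophin receptor, rose in basal forebrain at 3 months (1.11 ± 0.30, adjusted p = 0.0200). At 1 month, on the other array design, it differed by -1.47 ± 0.43 (adjusted p = 0.0596). Chat, the enzyme that makes acetylcholine, differed by at most 0.13 ± 0.05 (cortex at 3 months, adjusted p = 0.0470). Slc18a3, Gfap, Aif1, C1qa, Cd74, Mapt and Ttr passed in none of the 12 comparisons. Among the 8 to 13 immunoglobulin genes measured, Igh-1a fell in basal forebrain at 15 months (-0.74 ± 0.17, adjusted p = 0.0105).

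**Figure D1:**
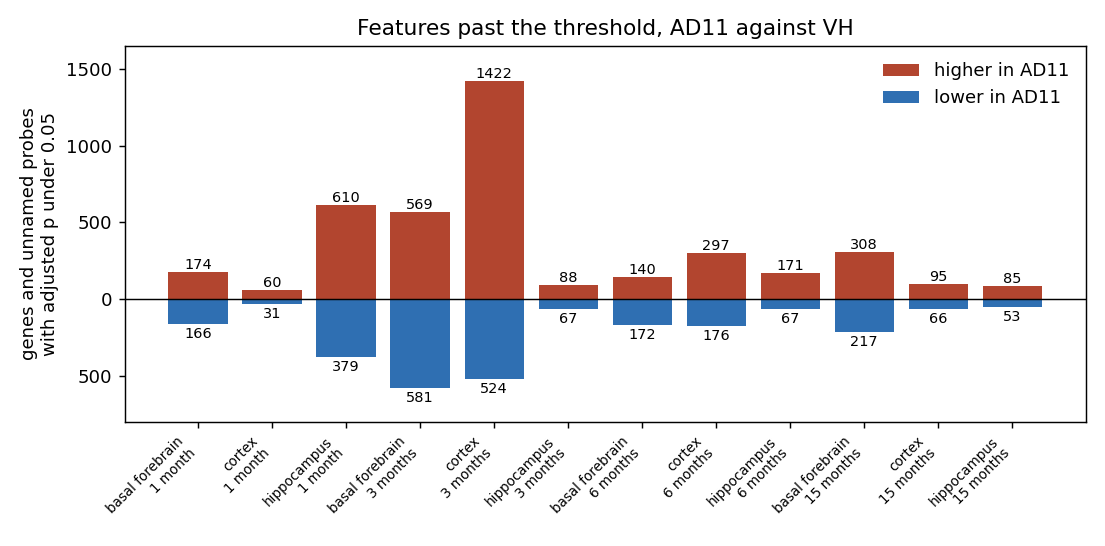
Number of genes and unnamed probes with an adjusted p under 0.05 in each comparison of AD11 with VH; bars above 0 count features higher in AD11 and bars below 0 those lower in AD11. The bars run from 60 higher and 31 lower in cortex at 1 month to 1422 higher and 524 lower in cortex at 3 months.

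At 1 month in basal forebrain, 174 of 19049 features rose in AD11 and 166 fell. Sox2ot, a long noncoding RNA transcribed across the Sox2 gene, rose by 1.60 ± 0.18 (adjusted p = 7.16e-09) and Mcemp1, a mast cell membrane protein, by 1.41 ± 0.23. The Riken transcript 9430027B09Rik was not well above background in VH and at least 2.53-fold higher in AD11. Mela, a melanoma antigen of retroviral origin, fell by 2.62 ± 0.57. H2-Q8, a nonclassical MHC class I gene, fell by 1.09 ± 0.22 and Prdm16, a transcriptional regulator, by 0.91 ± 0.22. Of 13 basal forebrain cholinergic markers 2 fell (Ntrk1 and Ache) and 11 did not pass, with 10 lower when adjusted over the list alone and a mean of -0.94. Of 18 striatum markers only Gpr6 fell (-1.06), 17 were lower when adjusted over the list alone, and their mean was -0.95. Of 19 hypothalamus markers Ecel1 (-0.77) and the transcription factor Nkx2-1 (-0.78) fell, and 3 were lower when adjusted over the list alone (set test adjusted p = 3.75e-05, adjusted p = 0.666 with an estimated correlation). Of 21 cortex markers the neuropeptide gene Vip rose (1.03), and 2 were higher when adjusted over the list alone (set test adjusted p = 0.00885, adjusted p = 0.731 with an estimated correlation). The set test placed the striatum list (adjusted p = 3.82e-10) and the cholinergic list (adjusted p = 4.22e-08) below other genes, but both had an adjusted p = 0.666 with an estimated correlation. The count of 340 became 178 with the slide as a random block and 55 within the slide shared by 3 AD11 arrays and 1 VH array. It was 68 after median centring (27 higher, 41 lower), 164 from the authors' deposited values (101 higher, 63 lower), and 76 with the striatum marker mean as a covariate against 135 from the basal forebrain arrays without it. It ran from 157 (without VH replicate 1) to 959 (without AD11 replicate 4), was 720 without VH replicate 2, which stood apart from its group, and 1011 without all arrays set apart in the series.

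At 1 month in cortex, 60 features rose and 31 fell. Mcemp1 (1.53 ± 0.23), Sox2ot (1.51 ± 0.18) and Wdfy1, an endosomal adaptor protein (1.02 ± 0.13, adjusted p = 2.27e-07), rose, and 9430027B09Rik was not well above background in VH and at least 2.71-fold higher in AD11. Pop4, a subunit of ribonuclease P (-0.68 ± 0.09), Slc7a8, an amino acid transporter (-0.68 ± 0.14), and the chemokine gene Ccl17 (-0.60 ± 0.12) fell. Of 21 genes of MHC class I and antigen processing, H2-T10 rose (0.73) and H2-Q1 fell (-0.56), and 2 were higher and 3 lower when adjusted over the list alone (set test adjusted p = 0.0253, adjusted p = 0.960 with an estimated correlation). Of 42 interferon-stimulated genes none passed, also when adjusted over the list alone, with a mean of -0.16 and a set test below other genes (adjusted p = 6.26e-05, and adjusted p = 0.960 with an estimated correlation). Within the slide that held 2 arrays of each genotype 18 passed, 65 passed within the shared scan day, and median centring left 15, all higher. The count was 110 without VH replicate 4, which stood apart from its group, and 145 without all arrays set apart.

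At 1 month in hippocampus, 610 features rose and 379 fell. Mcemp1 rose by 2.15 ± 0.23 (adjusted p = 7.65e-10), Sox2ot by 1.78 ± 0.18, C3, the central protein of the complement cascade, by 1.63 ± 0.37 and Cd300lf, a receptor of myeloid cells, by 1.59 ± 0.27. Mela was not well above background in AD11 and at least 4.38-fold lower there. Dusp16, a MAP kinase phosphatase, fell by 1.01 ± 0.21 and Slc7a8 by 0.88 ± 0.14. Of 24 postsynaptic density genes 3 fell, Homer2 (-0.56), Nlgn3 (-0.40) and Psd (-0.38), and 5 were lower when adjusted over the list alone (set test adjusted p = 0.00881, adjusted p = 0.932 with an estimated correlation). Of 93 oxidative phosphorylation genes 6 rose, Atp5mpl (0.57) among them, and 10 were higher and 2 lower when adjusted over the list alone (set test adjusted p = 0.00881, adjusted p = 0.932 with an estimated correlation). Of 21 MHC class I genes 4 fell, with H2-D1 at -0.66, and H2-T10 rose (0.86), and 8 were lower and 1 higher when adjusted over the list alone (set test adjusted p = 0.0329, adjusted p = 0.932 with an estimated correlation). All AD11 arrays were scanned on 1 day and all VH arrays on another, with no slide in common, so genotype and scan day cannot be told apart here. The count was 334 with the slide as a random block, 60 after median centring (54 higher, 6 lower), 62 from the arrays of these groups alone, and 458 without AD11 replicate 3. AD11 replicate 2 had a striatum marker mean of 1.39 and a cholinergic mean of 0.74, while both were under 0 in the others.

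At 3 months in basal forebrain, 569 of 18258 features rose and 581 fell. Sox2ot rose by 1.78 ± 0.12 (adjusted p = 3.71e-14), C3 by 1.73 ± 0.49, Itih5, a protein of the hyaluronan matrix, by 1.65 ± 0.26 and Dlk1, a Notch-related ligand, by 1.65 ± 0.39. Robo3, an axon guidance receptor, fell by 1.90 ± 0.35, Hkdc1, a hexokinase, by 1.90 ± 0.42, Prdm8, a transcriptional regulator, by 1.65 ± 0.27 and Nrn1, neuritin, by 1.45 ± 0.24. App, the amyloid precursor protein (-0.51 ± 0.13), Bdnf, a neurotrophin (-0.73 ± 0.18), and B2m (-0.44 ± 0.14) fell. Of 19 glutamatergic neuron genes 7 fell, led by the transcription factor genes Neurod6 (-1.64), Bhlhe22 (-1.28) and Neurod2 (-1.26) and by Nrgn (-1.20), and 12 were lower and 1 higher when adjusted over the list alone (set test adjusted p = 2.35e-08, adjusted p = 0.0690 with an estimated correlation). Of 21 cortex markers 6 fell, among them Fezf2 (-1.13) and Satb2 (-0.97), and 1 rose, with 13 lower and 1 higher when adjusted over the list alone (set test adjusted p = 3.58e-07, adjusted p = 0.296 with an estimated correlation). Of 19 hypothalamus markers 9 rose, galanin (Gal, 1.48) and Cartpt (1.17) among them, and 12 when adjusted over the list alone (set test adjusted p = 5.54e-09, adjusted p = 0.296 with an estimated correlation). Of 13 cholinergic markers Gal, Ngfr and Isl1 (0.97) rose, and 9 when adjusted over the list alone (set test adjusted p = 3.58e-07, adjusted p = 0.296 with an estimated correlation). The count of 1150 was 365 with the striatum marker mean as a covariate against 489 without it, 557 after median centring and 283 from the arrays of these groups alone. It ran from 585 (without VH replicate 2) to 1618 (without VH replicate 4).

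At 3 months in cortex, 1422 features rose and 524 fell, the highest count of the 12 comparisons, of which 765 and 459 were named genes. Sox2ot rose by 1.82 ± 0.12 (adjusted p = 1.12e-14), the Riken transcripts 6820402I19Rik and 9530083O12Rik by 1.81 ± 0.27 and 1.78 ± 0.33, Malat1, a nuclear noncoding RNA, by 1.75 ± 0.57 and C3 by 1.52 ± 0.49. Gabra2, a GABA-A receptor subunit, fell by 0.86 ± 0.25, H2-Q8 by 0.80 ± 0.19, Ccl17 by 0.75 ± 0.14 and Arhgef3 by 0.73 ± 0.09. Of 19 circadian clock genes Ciart (-0.37) and Bhlhe41 (-0.34) fell, and 3 were lower when adjusted over the list alone (set test adjusted p = 0.00829, adjusted p = 0.950 with an estimated correlation). Of 25 endothelial and pericyte genes Cldn5 (0.45), Flt1 (0.43) and Pdgfrb (0.30) rose, and 4 when adjusted over the list alone (set test adjusted p = 0.0398, adjusted p = 0.950 with an estimated correlation). The authors' deposited values gave 543 higher and 268 lower with the same model, and median centring gave 1312 higher and 1291 lower.

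At 3 months in hippocampus, 88 features rose and 67 fell. Itih5 (1.67 ± 0.26), Sox2ot (1.25 ± 0.12, adjusted p = 2.01e-09) and Mcemp1 (0.98 ± 0.12) rose, and Pop4 (-0.79 ± 0.10), H2-Q8 (-0.73 ± 0.19) and Wbp11, a splicing factor (-0.66 ± 0.10), fell. Of 37 interferon-stimulated genes Igtp fell (-0.53), the only member also when adjusted over the list alone (set test adjusted p = 0.00148, adjusted p = 0.974 with an estimated correlation). None of 93 oxidative phosphorylation genes passed, 7 were higher when adjusted over the list alone, and their mean was 0.07 (set test adjusted p = 2.85e-06, adjusted p = 0.974 with an estimated correlation). AD11 replicate 5 and VH replicate 5 stood apart from their groups. Without the former 1161 features passed, without the latter 128, and leaving out other arrays gave counts down to 95 (without VH replicate 4). The count was 375 without all arrays set apart, 87 after median centring and 37 from the arrays of these groups alone.

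At 6 months in basal forebrain (n = 5 and 4), 140 features rose and 172 fell. Soga1 rose by 1.21 ± 0.18 (adjusted p = 1.51e-05) and Sox2ot by 1.21 ± 0.19. The interferon-inducible GTPase genes Tgtp1 (-1.64 ± 0.46) and Irgm2 (-1.23 ± 0.24) fell, as did Prdm16 (-1.27 ± 0.24) and Traip, a ubiquitin ligase (-1.12 ± 0.22). Of 18 striatum markers Ido1 (-1.83) and Rasd2 (-0.80) fell, 16 were lower when adjusted over the list alone and the mean was -1.04, or -0.69 without AD11 replicate 3 (set test adjusted p = 1.25e-10, adjusted p = 0.612 with an estimated correlation). None of 13 cholinergic markers passed, 8 were lower when adjusted over the list alone and their mean was -0.87 (set test adjusted p = 3.41e-05, adjusted p = 0.612 with an estimated correlation). Of 42 interferon-stimulated genes Tgtp1 and Igtp (-1.09) fell, and 8 were lower and 1 higher when adjusted over the list alone (set test adjusted p = 0.000427, adjusted p = 0.658 with an estimated correlation). The count of 312 was 198 with the slide as a random block, and 245 within the slide of 1 AD11 and 3 VH arrays. It was 297 within the shared scan day, 41 after median centring (29 higher, 12 lower), 83 with the striatum marker mean as a covariate against 142 without it, and between 120 (without VH replicate 2) and 593 (without AD11 replicate 4).

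At 6 months in cortex, 297 features rose and 176 fell. 9430027B09Rik was not well above background in VH and at least 3.00-fold higher in AD11, and Sox2ot (1.63 ± 0.18, adjusted p = 5.56e-09), Abi3bp, a matrix protein (1.55 ± 0.35), and Mcemp1 (1.49 ± 0.23) rose. Of 42 interferon-stimulated genes 6 fell, led by Tgtp1 (-1.68 ± 0.43), Igtp (-1.15 ± 0.26), the guanylate-binding protein gene Gbp2 (-0.89) and Bst2 (-0.75), and 24 were lower and 1 higher when adjusted over the list alone, with a mean of -0.36 (set test adjusted p = 6.26e-14, adjusted p = 0.242 with an estimated correlation). Irgm2 (-1.13 ± 0.23) and H2-Q8 (-1.07 ± 0.22) fell as well. Of 21 GABAergic neuron genes the receptor subunit gene Gabra1 rose (0.58), and 2 were higher when adjusted over the list alone (set test adjusted p = 0.000214, adjusted p = 0.171 with an estimated correlation). Of 25 endothelial and pericyte genes Ly6c1 (-0.69) and Ly6a (-0.68) fell, and 3 were lower when adjusted over the list alone (set test adjusted p = 2.57e-05, adjusted p = 0.667 with an estimated correlation). Of 79 ribosomal protein genes 3 fell, Rps2 (-0.48) among them, also when adjusted over the list alone (set test adjusted p = 1.24e-09, adjusted p = 0.667 with an estimated correlation). The count of 473 was 201 with the slide as a random block and 30 within the slide of 1 AD11 and 3 VH arrays. It was 51 after median centring, 4741 with array weights, 199 without VH replicate 3, which stood apart from its group, and 796 without VH replicate 1.

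At 6 months in hippocampus, 171 features rose and 67 fell. C3 rose by 2.45 ± 0.37 (adjusted p = 8.36e-06), Mcemp1 by 1.89 ± 0.23, Sox2ot by 1.68 ± 0.18 and 9430027B09Rik by 1.51 ± 0.25. Acvr1c, an activin receptor (-1.13 ± 0.25), Slc7a14, an amino acid transporter (-0.96 ± 0.21), and Nnmt, nicotinamide N-methyltransferase (-0.92 ± 0.21), fell. No myelinating oligodendrocyte gene passed of 25, 7 were higher when adjusted over the list alone, and their mean was 0.30 (set test adjusted p = 8.55e-08, adjusted p = 0.811 with an estimated correlation). Of 25 heat shock and unfolded protein response genes none passed and 7 were lower when adjusted over the list alone, with a mean of -0.17 (set test adjusted p = 1.62e-05, adjusted p = 0.247 with an estimated correlation). The count of 238 was 117 with the slide as a random block and 5 within the slide of 3 AD11 arrays and 1 VH array. It was 53 after median centring (49 higher, 4 lower) and 121 without AD11 replicate 3.

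At 15 months in basal forebrain, 308 features rose and 217 fell. Sox2ot (1.44 ± 0.12, adjusted p = 1.63e-11), Mcemp1 (1.41 ± 0.12), Upb1, an enzyme of pyrimidine breakdown (1.16 ± 0.16), and H2-T10 (1.09 ± 0.14) rose. C1ra, a protease of the complement system (-0.84 ± 0.13), Urah, a urate pathway enzyme (-0.79 ± 0.15), and Pttg1, securin (-0.76 ± 0.06), fell. Of 18 striatum markers Drd1, the dopamine D1 receptor (1.06), Rarb (0.97), Pde1b (0.82) and Adora2a (0.16) rose, 15 were higher when adjusted over the list alone and the mean was 0.75, or 0.50 without VH replicate 5 (set test adjusted p = 2.90e-09, adjusted p = 0.892 with an estimated correlation). None of the 13 cholinergic markers passed, also when adjusted over the list alone, with a mean of 0.42, or 0.25 without VH replicate 5 (set test adjusted p = 0.00123, adjusted p = 0.892 with an estimated correlation). Of 21 MHC class I genes 4 rose, H2-T10 and H2-T23 (0.95) most, and 6 when adjusted over the list alone (set test adjusted p = 0.0330, adjusted p = 0.892 with an estimated correlation). The count of 525 was 81 with the striatum marker mean as a covariate against 295 without it, and 203 after median centring (162 higher, 41 lower). VH replicate 2 stood apart from its group: without it the count was 1160, without VH replicate 5 it was 220, and without all arrays set apart in the series 1743.

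At 15 months in cortex, 95 features rose and 66 fell. Sox2ot (1.44 ± 0.12, adjusted p = 4.23e-11), a T cell receptor segment, Trbv14 (1.28 ± 0.26), and Tnnt2, cardiac troponin T (1.22 ± 0.24), rose. C4b, a complement protein (-1.08 ± 0.27), and Prdm16 (-0.76 ± 0.20) fell. Of 21 MHC class I genes H2-T10 (1.14) and H2-T23 (0.97) rose, and 5 were higher and 1 lower when adjusted over the list alone (set test adjusted p = 0.000950, adjusted p = 0.893 with an estimated correlation). The count of 161 was 346 from the arrays of these groups alone, 70 after median centring, 706 with array weights and 103 without AD11 replicate 3.

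At 15 months in hippocampus, 85 features rose and 53 fell. Mcemp1 rose by 1.99 ± 0.23 (adjusted p = 1.61e-08), Sox2ot by 1.42 ± 0.18, H2-T10 by 1.10 ± 0.13 and Wdfy1 by 1.00 ± 0.13. Limch1, an actin-binding protein (-0.84 ± 0.16), Pttg1 (-0.76 ± 0.08), C4b (-0.73 ± 0.17) and Vars2, the mitochondrial valyl-tRNA synthetase (-0.63 ± 0.09), fell. Of 22 reactive astrocyte genes only C4b passed, also when adjusted over the list alone (set test adjusted p = 0.0286, adjusted p = 0.975 with an estimated correlation). The list mean turned to 0.038 with the slide as a fixed block. The count of 138 was 71 with the slide as a random block and 6 within the slide of 2 AD11 arrays and 1 VH array. It was 18 after median centring (17 higher, 1 lower) and 89 without VH replicate 4.

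The difference was also averaged over areas at each age, which a single area can carry, and arrays of different areas were taken as independent, an assumption, as the labels do not link arrays to animals. At 1 month 750 features rose and 637 fell (n = 15 and 15), with Mcemp1 (1.70 ± 0.13), Sox2ot (1.63 ± 0.10) and 9430027B09Rik (1.47 ± 0.14) highest among named genes and Mela (-2.27 ± 0.33), Tgtp1 (-1.24 ± 0.25) and S100a9, a neutrophil calcium-binding protein (-1.14 ± 0.28), lowest. Mapt, which encodes tau, fell by 0.20 ± 0.06 (adjusted p = 0.0242). Of 21 MHC class I genes 8 fell, with H2-D1 (-0.61) and H2-K1 (-0.56), and 2 rose, and 10 were lower and 3 higher when adjusted over the list alone (set test adjusted p = 0.00591, adjusted p = 0.923 with an estimated correlation). At 3 months 1010 features rose and 729 fell (n = 15 and 15). C3 rose by 1.66 ± 0.28, Itih5 by 1.54 ± 0.15 and C1qa, a complement protein of microglia, by 0.27 ± 0.08. Pop4 (-0.76 ± 0.06), H2-Q8 (-0.73 ± 0.11) and App (-0.29 ± 0.08) fell. Of 19 clock genes 7 fell, with Per1 (-0.48), Bhlhe40 (-0.44) and Hlf (-0.41), and 1 rose, and 9 were lower and 1 higher when adjusted over the list alone (set test adjusted p = 3.96e-05, adjusted p = 0.197 with an estimated correlation). Of 26 homeostatic microglia genes 5 rose, Laptm5 (0.31) and Trem2 (0.29) among them, also when adjusted over the list alone (set test adjusted p = 0.0455, adjusted p = 0.907 with an estimated correlation). Median centring turned this split to 919 higher and 1105 lower.

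At 6 months 671 features rose and 679 fell on average over areas (n = 15 and 14). C3 rose by 1.66 ± 0.22 (adjusted p = 5.82e-08), Shisa3 by 1.25 ± 0.27 and Tnnt2 by 1.20 ± 0.20. Of 42 interferon-stimulated genes 17 fell, with Tgtp1 (-1.57 ± 0.26), Igtp (-1.03 ± 0.15), Gbp3 (-0.85 ± 0.16) and Gbp2 (-0.74 ± 0.14) lowest, and 1 rose, and 24 were lower and 1 higher when adjusted over the list alone (set test adjusted p = 5.01e-12, adjusted p = 0.371 with an estimated correlation). Of 26 homeostatic microglia genes 8 fell, Gpr34 (-0.45) and the purine receptor gene P2ry12 (-0.36) among them, and 9 when adjusted over the list alone (set test adjusted p = 9.07e-05, adjusted p = 0.835 with an estimated correlation). Of 25 heat shock and unfolded protein response genes 8 fell, Creld2 (-0.37) and Sdf2l1 (-0.36) among them, and 11 when adjusted over the list alone (set test adjusted p = 0.000931, adjusted p = 0.371 with an estimated correlation). The count was 766 with the slide as a random block and 280 after median centring. At 15 months, over basal forebrain and cortex (n = 10 and 10), 271 features rose and 198 fell. Prl, prolactin, rose by 2.40 ± 0.53 (adjusted p = 0.00350), H2-T10 by 1.12 ± 0.10 and H2-T23 by 0.96 ± 0.15, and the complement genes C2 (-0.92 ± 0.21), C4b (-0.89 ± 0.19) and C1ra (-0.45) fell. These were the 3 members that fell of 17 complement genes, also when adjusted over the list alone (set test adjusted p = 0.0273, adjusted p = 0.937 with an estimated correlation).

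A group of genes differed in the same direction in many ages and areas. Of 16589 named genes measured on either design, 67 rose and 32 fell in at least 6 of the 12 comparisons. Sdc4, among the 67, fell in 4 others, where another probe had been chosen. In the authors' table Ube2d-ps, lower in 11, differed by 0.62 to 0.92, and Tmem260, lower in 10, by -0.077 to 0.26. Another probe may stand there: further Ube2d-ps probes had means of -0.24 to 0.79. In all 12 comparisons, 1810014B01Rik, Fam71e1, Gm5148, Hars (histidyl-tRNA synthetase), Mcemp1, Nosip, Soga1, Sox2ot, Tmem254a and Wdfy1 rose, and Alad (an enzyme of haem synthesis), Dpy19l3, Gdf9, Nudt19, Pop4 and Pttg1 fell. Where these 99 genes had a further kept probe, that probe showed a median of 0.114 of the chosen probe's difference over 102 probe pairs. Averaged over comparisons with 1 and with 4 arrays per slide, the differences of Sox2ot were 1.55 and 1.55 for the chosen probe, and 0.15 and 0.21 or 0.055 and -0.043 for the others. Nosip had 0.52 and 0.58 against -0.14 and -0.24, Hars 0.79 and 0.54 against 0.062 and -0.056, and 1810014B01Rik 0.72 and 0.85 against -0.030 and 0.093. With 1 array per slide Mcemp1 had 1.16 against -0.0099 and Alad -0.48 against -0.016. For Pop4 (-0.71 and -0.66 against -0.52 and -0.49) the probes ran alike, as they did for Wdfy1 (1.01 and 1.03 against 0.81 and 0.80), apart from a further probe at -0.10.

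**Figure D2:**
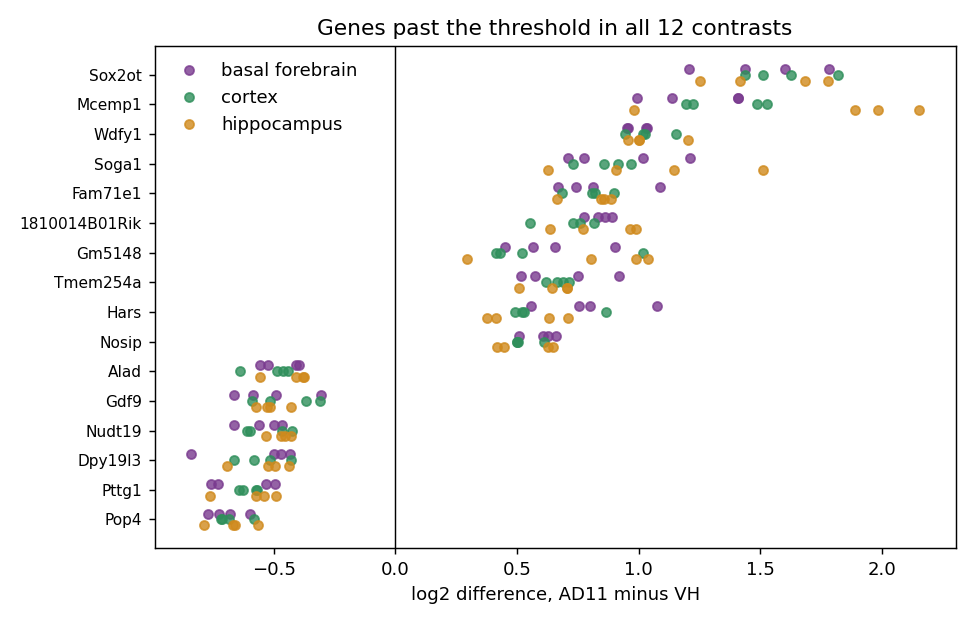
Log2 difference of AD11 minus VH for the 16 genes that passed in all 12 comparisons, with 1 point for each comparison, coloured by brain area. The 10 genes higher in AD11 lie right of 0 and the 6 lower genes left of 0 at every point.

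The question of whether the genotype difference changed with age was tested as an interaction within an array design. In hippocampus genotype and scan day coincided at 1 month, so the interaction includes any difference between those days. There the difference at 6 months was higher than at 1 month for 31 features, with Stk25 (0.87 ± 0.20), Kdm4a, a histone demethylase (0.83 ± 0.15), and Cntn2, a cell adhesion protein (0.79 ± 0.17). It was lower for 28, with Fam98b (-0.77 ± 0.16), the translation factor gene Eif3e (-0.73 ± 0.14) and Faf2 (-0.65 ± 0.15). In cortex the difference at 15 months was higher than at 3 months for 64 features, with the clock genes Ciart (0.79 ± 0.18) and Dbp (0.59 ± 0.16). It was lower for 491, with 9530091C08Rik (-2.02 ± 0.41) and 6330415B21Rik (-1.95 ± 0.51). The limma test found 0 features in basal forebrain and cortex for 6 against 1 month, in basal forebrain for 15 against 3 months and in hippocampus for 15 against 6 months, with 1647, 634, 1723 and 866 at an unadjusted p under 0.05. The lowest unadjusted p there belonged to Ndfip1 (adjusted p = 0.0598), Gm5148 (adjusted p = 1.00), Apex2 (adjusted p = 0.162) and 3300002A11Rik (adjusted p = 0.747). The hippocampus count of 59 was 41 with the scanner software's log ratio (17 higher, 24 lower), 4 with the slide as a random block, 0 after median centring and 2 without AD11 replicate 3 at 1 month. The cortex count of 555 was 96 from the authors' deposited values, 231 without VH replicate 3 at 3 months and 1060 without VH replicate 1 at 3 months. With array weights the 4 counts of 0 became 421, 632, 508 and 6.

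Age differences in VH mice give a scale for the genotype differences, although no such comparison shared a scan day, so age and scan day cannot be told apart. From 1 to 6 months Il33, an alarmin cytokine, rose by 1.56 ± 0.18 in basal forebrain (n = 4 and 5) and 1.45 ± 0.17 in cortex, C4b by 1.41 ± 0.17 in cortex and Abca8a, a lipid transporter, by 1.65 ± 0.21 in basal forebrain. The haemoglobin genes Hbb-bt (-2.27 ± 0.67) and Hba-a1 (-1.97 ± 0.51) fell in basal forebrain, and Gsn, gelsolin, fell in cortex (-1.37 ± 0.18) and hippocampus (-1.72 ± 0.18). In all, 416 features rose and 450 fell in basal forebrain, 204 and 203 in cortex, and 1099 and 1043 in hippocampus, where Cox8b rose by 2.01 ± 0.42 and Clic6, a choroid plexus gene, by 1.99 ± 0.66, and Syt10 fell by 1.98 ± 0.43. The choroid plexus mean in VH hippocampus was under 0 in 4 of 5 arrays at 1 month and over 0 in 4 of 5 at 6 months. From 3 to 15 months 925 rose and 968 fell in basal forebrain, with Pisd-ps3 (1.35 ± 0.14) and the myelin gene Plp1 (-1.18 ± 0.36), and 1818 rose and 1856 fell in cortex, with Malat1 (1.74 ± 0.57), C4b (1.48 ± 0.27) and Clip2 (-1.10 ± 0.13). The VH cortex arrays at 3 months enter both this Malat1 difference and that of genotype at 3 months. From 6 to 15 months 585 rose and 479 fell in hippocampus, with Nell2 (1.82 ± 0.25) and Ptov1 (-1.14 ± 0.16). With the slide as a random block the counts on the design with 4 arrays per slide were 299, 173, 1007 and 224 in place of 866, 407, 2142 and 1064. Median centring split the features of 15 against 3 months into 454 higher and 3151 lower in basal forebrain and 1491 higher and 8092 lower in cortex.

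The marker means of the basal forebrain arrays belong to lists whose calls were all lost with an estimated correlation. The striatum marker mean was 0.01 ± 0.83 in AD11 and 0.96 ± 0.28 in VH at 1 month (SD, n = 5 each), 1.31 ± 0.34 and 1.06 ± 0.38 at 3 months, -5.34e-05 ± 1.04 and 1.04 ± 0.70 at 6 months (n = 5 and 4), and 1.15 ± 0.40 and 0.40 ± 0.68 at 15 months. The cholinergic marker mean was -0.41 ± 0.53 and 0.53 ± 0.79 at 1 month, 0.95 ± 0.23 and 0.28 ± 0.42 at 3 months, -0.21 ± 0.87 and 0.66 ± 0.28 at 6 months, and 0.38 ± 0.48 and -0.04 ± 0.51 at 15 months. The hypothalamus mean was 0.74 ± 0.66 in AD11 and -0.035 ± 0.72 in VH at 3 months. Within groups the striatum and cholinergic means rose and fell together over the 39 arrays (r = 0.603, permutation p = 0.000400, adjusted 0.000800; rho = 0.550, permutation p = 0.000890, adjusted 0.00178; 2 relations tested), and r was 0.598 without the 2 arrays farthest from the median. The striatum and cortex means had r = -0.215 (permutation p = 0.204) and rho = -0.211 (permutation p = 0.218), and r = -0.212 without those 2 arrays.

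**Figure D3:**
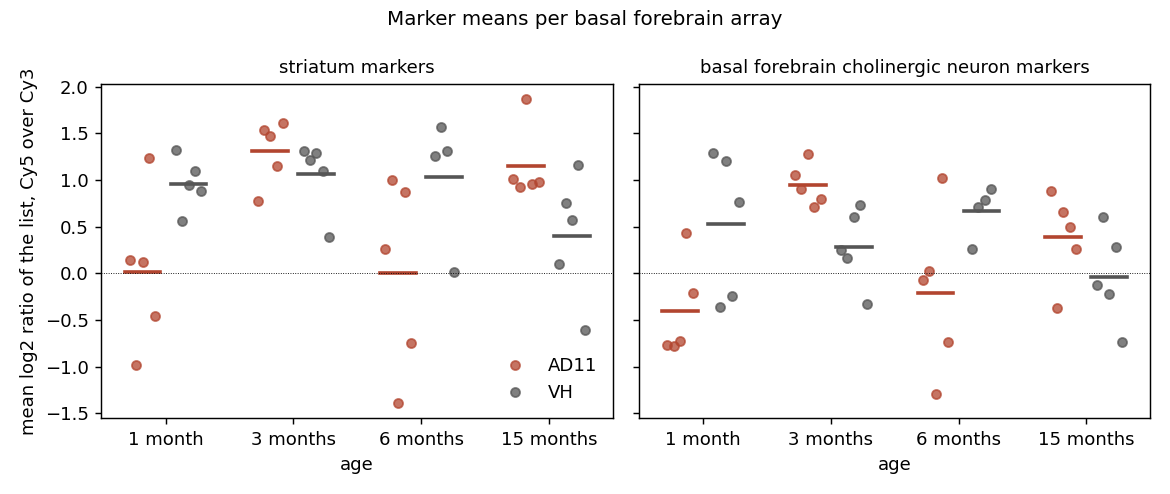
Mean log2 ratio (Cy5 over Cy3) of the striatum markers and of the cholinergic markers on each basal forebrain array, by age; points are arrays and bars are group means. The AD11 striatum mean lies at 0.01 against 0.96 in VH at 1 month and at 1.15 against 0.40 at 15 months.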

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

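The tests of neighbouring genes, of the covariates, of a loss of cholinergic neurons and of the probes behind Sdc4 and Gemin5 were chosen only after the result was seen. The tests of other splits of the arrays, of further probes of a gene and of the share of striatum were set before.

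Within each group of 4 or 5 arrays the array at either end was set against the others for 9 measures, and the gap to the next array as a share of the whole range marked 34 values in 203 such comparisons. Chance alone marks about 1 in 20 groups, as both ends were tested.

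The log2 ratio of C3 lay apart at 0.065 in AD11 basal forebrain 15 months replicate 1 (others -1.60 to -1.29), 1.94 in VH basal forebrain 15 months replicate 2 (others -2.83 to -2.25), -2.10 in VH basal forebrain 6 months replicate 4 (others -2.96 to -2.85), -1.09 in VH cortex 1 month replicate 4 (others -3.27 to -2.76) and -2.67 in VH cortex 15 months replicate 1 (others -2.28 to -2.14). The log2 ratio of Chat lay apart at 0.23 in VH hippocampus 15 months replicate 2 (others -0.012 to 0.0093). The log2 ratio of Ngf lay apart at 0.11 in AD11 cortex 15 months replicate 4 (others -0.078 to -0.060), -0.51 in AD11 cortex 3 months replicate 2 (others 0.090 to 0.20), -0.35 in AD11 hippocampus 1 month replicate 2 (others 0.38 to 0.67), 0.34 in VH cortex 3 months replicate 2 (others 0.092 to 0.16) and 0.51 in VH cortex 6 months replicate 3 (others -0.012 to 0.053). The log2 ratio of Ngfr lay apart at 0.38 in AD11 basal forebrain 1 month replicate 4 (others -1.60 to -1.07), 1.11 in AD11 hippocampus 1 month replicate 2 (others -1.39 to -0.90) and -0.26 in AD11 hippocampus 3 months replicate 2 (others -1.06 to -0.82).

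The log2 ratio of Ntrk1 lay apart at 0.30 in AD11 basal forebrain 1 month replicate 4 (others -1.09 to -0.76), 0.65 in AD11 hippocampus 1 month replicate 2 (others -1.38 to -1.08) and -0.052 in VH cortex 1 month replicate 4 (others -0.97 to -0.81). The log2 ratio of Ttr lay apart at -2.90 in AD11 basal forebrain 6 months replicate 1 (others -3.89 to -3.63), -3.33 in AD11 cortex 1 month replicate 5 (others 0.65 to 1.67), -3.30 in AD11 cortex 3 months replicate 5 (others 0.088 to 1.22), -3.21 in VH cortex 1 month replicate 5 (others -0.024 to 0.78) and 2.34 in VH hippocampus 1 month replicate 1 (others -2.52 to -2.19). The mean correlation with the other arrays of the group was 0.814 in AD11 hippocampus 15 months replicate 1 (others 0.854 to 0.868), 0.492 in AD11 hippocampus 3 months replicate 5 (others 0.713 to 0.793), 0.740 in VH basal forebrain 1 month replicate 2 (others 0.812 to 0.833), 0.511 in VH basal forebrain 15 months replicate 2 (others 0.754 to 0.759), 0.661 in VH cortex 1 month replicate 4 (others 0.820 to 0.840), 0.452 in VH cortex 6 months replicate 3 (others 0.755 to 0.789), 0.682 in VH hippocampus 15 months replicate 5 (others 0.797 to 0.824) and 0.361 in VH hippocampus 3 months replicate 5 (others 0.628 to 0.713). The share of probes well above background in Cy5 was 62.0% in AD11 hippocampus 3 months replicate 5 (others 60.2% to 60.7%). The share of saturated Cy5 spots was 0.152% in AD11 basal forebrain 15 months replicate 3 (others 0.0385% to 0.0482%), 0.0891% in AD11 hippocampus 3 months replicate 3 (others 0.0626% to 0.0674%) and 0.0023% in VH cortex 1 month replicate 4 (others 0%).

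In the interactions 59 features passed in hippocampus between 1 and 6 months and 555 in cortex between 3 and 15 months, against 0 in the other 4. The 59 include any difference between the scan days of the genotypes at 1 month, and were 4 with the slide as a random block and 0 after median centring.

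For each comparison 100 splits of its arrays were fitted, the true split included, and those with as many features as the true split were counted. Brackets give features, splits with as many and the highest count of the other splits. Fewer than 5 splits gave as many (unadjusted for 28 comparisons) for cortex at 1 month (91, 1, 53), hippocampus at 1 month (989, 1, 363), basal forebrain at 3 months (1150, 1, 775), cortex at 3 months (1946, 1, 1320), basal forebrain at 6 months (312, 2, 704), hippocampus at 6 months (238, 1, 115), basal forebrain at 15 months (525, 3, 2052), cortex at 15 months (161, 1, 8), hippocampus at 15 months (138, 1, 84), the mean over areas at 1 month (1387, 1, 206), the mean over areas at 3 months (1739, 1, 744), the mean over areas at 6 months (1350, 1, 286) and the mean of basal forebrain and cortex at 15 months (469, 1, 90). The same held for the hippocampus interaction of 6 against 1 month (59, 4, 211), the cortex interaction of 15 against 3 months (555, 1, 254), VH basal forebrain, 6 against 1 month (866, 1, 217), VH cortex, 6 against 1 month (407, 2, 1014), VH hippocampus, 6 against 1 month (2142, 1, 521), VH basal forebrain, 15 against 3 months (1893, 2, 2223), VH cortex, 15 against 3 months (3674, 1, 1254) and VH hippocampus, 15 against 6 months (1064, 1, 141). In hippocampus at 1 month, which also enters the mean over areas and the interaction, the true split was that of scan days and slides, and in the VH comparisons that of scan days, so a batch is not excluded there. Splits ignored the slide, and with 4 arrays per slide the genotypes of a comparison shared at most 1 slide, so a difference between slides is not excluded there either. With the slide as a random block those counts were 178, 69 and 334 at 1 month and 198, 201 and 117 at 6 months in basal forebrain, cortex and hippocampus, and 71 in hippocampus at 15 months.

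Chance stayed open where another split gave more. It also did, at 5 splits or more, for basal forebrain at 1 month (340, 6, 1954), hippocampus at 3 months (155, 19, 5005) and cortex at 6 months (473, 5, 871). For comparisons with 0 features any split gives at least 0, so all 100 splits gave as many and this count says nothing: the basal forebrain interaction of 6 against 1 month (highest other 319), the cortex interaction of 6 against 1 month (highest other 48), the basal forebrain interaction of 15 against 3 months (highest other 1661) and the hippocampus interaction of 15 against 6 months (highest other 103). In cortex at 6 months 1 of the splits with as many features kept the arrays of a slide together, as did 1 for VH cortex, 6 against 1 month. Some splits had several times the true count in hippocampus at 3 months and basal forebrain at 1 and 15 months. They point to a structure among the arrays other than genotype. In hippocampus at 3 months this may be AD11 replicate 5, without which the count was 1161.

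The first pattern weighed was the 67 genes higher and 32 lower in at least 6 of 12 comparisons. Of the 88 genes placed on GRCm38.p6, 39 lay within 10 measured genes of another, against a median of 9 and at most 29 in 10000 random sets, of which 0 reached 39, and 36 against at most 26 when genes of like names were not counted as neighbours. The longest runs were Dusp16, Cdkn1b, Pbp2, Atf7ip and Pde6h on chromosome 6 and Nudt19, Dpy19l3, Pop4 and Zfp939 on chromosome 7, so linked segments of different parental origin in the 2 lines are a candidate explanation. Sequence variants under single probes could not be told from other differences of probes, because the further probes showed a median of 0.114 of the difference, 22 of 102 over 0.5 of it, while age differences in VH cortex showed 0.163 and VH hippocampus against cortex 0.532, yardsticks chosen after the data were seen. An effect of the antibody at every age and area remains open and was not tested apart from these.

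The second pattern was the markers of striatum and cholinergic neurons in basal forebrain, where the striatum difference ran from -1.04 at 6 months (-0.69 without AD11 replicate 3) to 0.75 at 15 months (0.50 without VH replicate 5). A share of striatum that varies between dissected pieces predicts a spread within groups of at least 0.5 of the median absolute difference, and the SD within groups was 0.632, or 0.743 of that difference (0.850). A loss of cholinergic neurons predicts no rise, and the cholinergic mean was higher in AD11 with a set test call at 2 of 4 ages, by 0.66 at 3 months and 0.42 at 15 months (0.25 without VH replicate 5), both calls lost with an estimated correlation (adjusted p = 0.296 and 0.892). With the striatum and hypothalamus means as covariates and without Gal, a gene of both lists, the differences (± standard error) at 1, 3, 6 and 15 months went from -0.94 ± 0.42, 0.60 ± 0.26, -0.92 ± 0.45 and 0.43 ± 0.26 to -0.10 ± 0.15, 0.24 ± 0.14, -0.30 ± 0.16 and 0.036 ± 0.15, with 0 ages higher by over 2 standard errors, so a loss and a varying dissection cannot be told apart, as the covariates differ by genotype too. A varying dissection stays a candidate explanation of these markers. With the striatum covariate features that had passed kept a median of 0.892, 0.953, 0.947 and 0.895 of their differences at the 4 ages. Carried-over cortex or hypothalamus was not tested for these features.

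The third pattern was Sdc4 and Gemin5, which passed in opposite directions on the 2 array designs, where a different probe had been chosen. The probe of Sdc4 chosen with 4 arrays per slide was higher in 9 comparisons (0.32 to 1.14) and the other lower in 8 (-0.90 to -0.54), and those of Gemin5 were higher in 9 (0.25 to 0.36) and lower in 6 (-0.32 to -0.13). With the same probe on both designs 0 of the 2 genes differed in direction, so the choice of probe accounts for the reversal, while the direction of both genes stays unknown.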

How the results depend on the processing

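The alternatives were fixed before the data were examined, except for leaving aside the arrays that stood apart in their group, the striatum and hypothalamus marker means as covariates and the basal forebrain arrays alone, which were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that join arrays of different groups. Where a count or sign changed, the cause was not tested, except that leaving out arrays lowers the number of values by construction, and except for the covariate. The median spot lay between 1.61 and 2.31 times its local background in Cy5 with 1 array per slide and between 2.12 and 4.50 times with 4 arrays per slide, so differences of dim probes were least precise.

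Aquantile scaling between arrays acts on mean intensities alone and cannot move a log ratio, so it was no test of the results. No filter on dim probes and a trended, robust prior left each of the 28 counts within 1.5 times its value, and without the filter 120 gene calls ended and 33 list calls were added. The number of genes that differed the same way in at least 6 of 12 comparisons was 99, and also 99 with only the probes named alike on both array designs, but how many genes were shared was not counted. With camera at an estimated correlation 0 of the 126 list calls passed, and 19 tests passed in fry. The striatum list has no value under its own mean as a covariate, which holds it at 0.

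Among the 2001 named gene values, or fewer where stated, the calls that ended and the calls that were added numbered 761 and 9 with median centring in place of loess, 80 and 57 with the scanner software's log ratio, 21 and 49 with no background correction before loess, 72 and 32 with the authors' table with the same model (of 1466), 543 and 26 with a fit of only the arrays compared, 236 and 0 with the slide as a random block (of 1147), 496 and 0 with the slide as a fixed block (of 884), 32 and 6 with the scan day as a block (of 1726), 36 and 197 with array quality weights, 200 and 13 with the mean of all kept probes of a gene, 65 and 44 with leaving aside the 8 arrays set apart (of 1125), 226 and 0 with the striatum marker mean as a covariate (of 601) and 161 and 2 with the basal forebrain arrays alone (of 601). Each array left out in turn ended 1574 and added 47 of 14837. The median difference of all genes moved by over 0.1 with median centring: to -0.13 in basal forebrain at 1 month, -0.11 in cortex at 3 months, -0.13 in the cortex interaction of 6 against 1 month, 0.13 in VH cortex, 6 against 1 month, 0.13 in VH hippocampus, 6 against 1 month, -0.11 in VH basal forebrain, 15 against 3 months, -0.24 in VH cortex, 15 against 3 months and -0.14 in VH hippocampus, 15 against 6 months.

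Median centring in place of loess gave 68 in basal forebrain, 15 in cortex, 60 in hippocampus and 223 in the mean over areas at 1 month, 557 in basal forebrain and 87 in hippocampus at 3 months, 41 in basal forebrain, 51 in cortex, 53 in hippocampus and 280 in the mean over areas at 6 months and 203 in basal forebrain, 70 in cortex, 18 in hippocampus and 247 in the mean of basal forebrain and cortex at 15 months, and for the interactions 0 in hippocampus for 6 against 1 month and 1 in basal forebrain for 15 against 3 months, and in VH 25 in basal forebrain, 13 in cortex and 278 in hippocampus for 6 against 1 month, 3605 in basal forebrain and 9583 in cortex for 15 against 3 months and 47 in hippocampus for 15 against 6 months. Signs turned for oxidative phosphorylation (0.16 in cortex at 1 month, -0.031 in basal forebrain at 15 months and -0.10 in the mean over areas at 3 months) and cytosolic ribosomal proteins (-0.22 in cortex at 3 months).

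The scanner software's log ratio gave 177 in cortex at 1 month, 711 in cortex at 6 months and 229 in hippocampus at 15 months, and for the interactions 1 in hippocampus for 15 against 6 months, and in VH 710 in cortex for 6 against 1 month.

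No background correction before loess gave 182 in cortex at 1 month, and in VH 741 in cortex for 6 against 1 month.

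The authors' table with the same model gave 164 in basal forebrain at 1 month, 811 in cortex and 994 in the mean over areas at 3 months, 133 in hippocampus at 6 months and 348 in basal forebrain and 107 in cortex at 15 months, and for the interactions 96 in cortex for 15 against 3 months. Signs turned for Tmem260 (0.19 in basal forebrain and 0.26 in hippocampus at 1 month, 0.060 in basal forebrain and 0.044 in cortex at 3 months, 0.12 in basal forebrain, 0.13 in cortex and 0.13 in hippocampus at 6 months and 0.026 in basal forebrain and 0.13 in hippocampus at 15 months), Ube2d-ps (0.92 in basal forebrain, 0.82 in cortex and 0.69 in hippocampus at 1 month, 0.71 in basal forebrain, 0.82 in cortex and 0.76 in hippocampus at 3 months, 0.62 in basal forebrain, 0.79 in cortex and 0.77 in hippocampus at 6 months and 0.70 in basal forebrain, 0.83 in cortex and 0.84 in hippocampus at 15 months) and Sdc4 (0.57 in basal forebrain, 0.79 in cortex, 0.30 in hippocampus and 0.56 in the mean over areas at 3 months and 0.53 in basal forebrain, 0.58 in cortex and 0.56 in the mean of basal forebrain and cortex at 15 months).

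A fit of only the arrays compared gave 57 in basal forebrain, 57 in cortex, 62 in hippocampus and 835 in the mean over areas at 1 month, 283 in basal forebrain, 37 in hippocampus and 1064 in the mean over areas at 3 months, 130 in basal forebrain and 116 in cortex at 6 months and 160 in basal forebrain, 346 in cortex and 59 in hippocampus at 15 months, and for the interactions 0 in hippocampus for 6 against 1 month and 1391 in cortex for 15 against 3 months, and in VH 56 in cortex for 6 against 1 month and 926 in basal forebrain and 5754 in cortex for 15 against 3 months.

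The slide as a random block gave 178 in basal forebrain and 334 in hippocampus at 1 month, 198 in basal forebrain, 201 in cortex, 117 in hippocampus and 766 in the mean over areas at 6 months and 71 in hippocampus at 15 months, and for the interactions 4 in hippocampus for 6 against 1 month, and in VH 299 in basal forebrain, 173 in cortex and 1007 in hippocampus for 6 against 1 month and 224 in hippocampus for 15 against 6 months.

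The slide as a fixed block gave 56 in basal forebrain and 18 in cortex at 1 month, 30 in cortex, 5 in hippocampus and 178 in the mean over areas at 6 months and 6 in hippocampus at 15 months, and for the interactions 45 in basal forebrain for 6 against 1 month and 1 in hippocampus for 15 against 6 months. Signs turned for cytosolic ribosomal proteins (-0.022 in basal forebrain and -0.16 in cortex at 1 month and 0.050 in hippocampus at 6 months), endothelium and pericytes (0.13 in basal forebrain at 1 month), immediate early genes (-0.42 in basal forebrain at 1 month), homeostatic microglia (-0.12 in cortex at 1 month and 0.0068 in basal forebrain at 6 months), red blood cells (-0.78 in cortex at 1 month), MHC class I and antigen processing (0.16 in basal forebrain at 6 months), reactive astrocytes (0.33 in basal forebrain at 6 months and 0.038 in hippocampus at 15 months), interferon-stimulated genes (0.0033 in hippocampus at 6 months), choroid plexus (1.97 in hippocampus at 15 months), meninges and fibroblasts (0.57 in hippocampus at 15 months), MHC class II (0.28 in hippocampus at 15 months), astrocytes (0.040 in the mean over areas at 6 months), Aif1 (0.016 in the mean over areas at 6 months) and Slc1a3 (0.057 in the mean over areas at 6 months).

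The scan day as a block moved only the interaction count, to 1 in basal forebrain for 6 against 1 month.

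Array quality weights gave 1934 in basal forebrain and 389 in cortex at 1 month, 3216 in basal forebrain, 5480 in cortex, 297 in hippocampus and 3816 in the mean over areas at 3 months, 2327 in basal forebrain, 4741 in cortex, 578 in hippocampus and 4406 in the mean over areas at 6 months and 3581 in basal forebrain, 706 in cortex, 579 in hippocampus and 2188 in the mean of basal forebrain and cortex at 15 months, and for the interactions 421 in basal forebrain, 632 in cortex and 121 in hippocampus for 6 against 1 month, 508 in basal forebrain and 3254 in cortex for 15 against 3 months and 6 in hippocampus for 15 against 6 months, and in VH 3732 in basal forebrain, 3529 in cortex and 4533 in hippocampus for 6 against 1 month, 5166 in basal forebrain and 7895 in cortex for 15 against 3 months and 3881 in hippocampus for 15 against 6 months. Signs turned for cytosolic ribosomal proteins (-0.013 in hippocampus at 1 month and 0.045 in basal forebrain at 3 months).

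The mean of all kept probes of a gene moved only the interaction count, to 25 in hippocampus for 6 against 1 month. Signs turned for Lrp6 (-0.067 in basal forebrain and -0.11 in the mean over areas at 1 month and -0.069 in cortex at 3 months), Ube2d-ps (0.056 in cortex and 0.030 in hippocampus at 1 month, 0.052 in cortex and 0.10 in hippocampus at 3 months, 0.0081 in hippocampus at 6 months and 0.058 in cortex at 15 months), Atf7ip (-0.026 in hippocampus at 1 month), H2-Q1 (0.13 in hippocampus and 0.10 in the mean over areas at 1 month and 0.14 in cortex at 6 months), Rpl21 (0.29 in hippocampus at 1 month), Ttc5 (-0.044 in hippocampus at 1 month), Tmem260 (0.0089 in basal forebrain at 3 months), Sdc4 (0.094 in cortex at 3 months and -0.014 in hippocampus at 15 months), Gadd45gip1 (-0.0052 in cortex at 6 months) and Ndufa12 (-0.023 in the mean over areas at 1 month).

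Leaving aside the 8 arrays set apart gave 1011 in basal forebrain and 145 in cortex at 1 month, 375 in hippocampus at 3 months, 240 in cortex at 6 months and 1743 in basal forebrain and 751 in the mean of basal forebrain and cortex at 15 months, and in VH 251 in cortex for 6 against 1 month and 3403 in basal forebrain for 15 against 3 months. Signs turned for reactive astrocytes (0.019 in basal forebrain at 15 months) and interferon-stimulated genes (0.065 in the mean of basal forebrain and cortex at 15 months).

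The striatum marker mean as a covariate gave 76 in basal forebrain at 1 month, 365 in basal forebrain at 3 months, 83 in basal forebrain at 6 months and 81 in basal forebrain at 15 months. Basal forebrain arrays alone, without the covariate, gave 135, 489, 142 and 295, and 505 in VH for 6 against 1 month. At the 4 ages the features that had passed had a median absolute difference of 0.48, 0.40, 0.51 and 0.36 (median standard error 0.11, 0.11, 0.12 and 0.085) without the covariate and 0.40, 0.38, 0.45 and 0.31 (0.12, 0.11, 0.13 and 0.098) with it. Calls thus ended by smaller differences and, except at 3 months, also by larger errors.

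Within the slide that held both genotypes, the counts were 55 in basal forebrain at 1 month, 18 in cortex at 1 month, 30 in cortex at 6 months, 5 in hippocampus at 6 months and 6 in hippocampus at 15 months, and the sign changes were those of the fixed block in these comparisons. The slides left few arrays: the lone array of a genotype was assumed to vary like the other groups.

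Leaving out each array in turn gave the following ranges, with each array that moved a count by over 1.5 times. For basal forebrain at 1 month it ran from 157 to 959, moved by AD11 replicates 2 (224) and 4 (959), VH replicates 1 (157), 2 (720) and 3 (183). For hippocampus at 1 month it ran from 458 to 1082, moved by AD11 replicate 3 (458), VH replicates 2 (631), 4 (639) and 5 (584). For basal forebrain at 3 months it ran from 585 to 1618, moved by AD11 replicates 1 (765) and 3 (623), VH replicates 1 (609), 2 (585) and 5 (744). For hippocampus at 3 months it ran from 95 to 1161, moved by AD11 replicates 3 (96), 4 (98) and 5 (1161), VH replicate 4 (95). For basal forebrain at 6 months it ran from 120 to 593, moved by AD11 replicates 1 (206), 3 (183) and 4 (593), VH replicates 1 (191), 2 (120) and 3 (184). For cortex at 6 months it ran from 199 to 796, moved by AD11 replicates 1 (206), 2 (208) and 3 (226), VH replicates 1 (796), 3 (199) and 5 (710). For hippocampus at 6 months it ran from 121 to 252, moved by AD11 replicate 3 (121), VH replicate 4 (152). For basal forebrain at 15 months it ran from 220 to 1160, moved by AD11 replicates 3 (283), 4 (322) and 5 (327), VH replicates 1 (237), 2 (1160), 3 (815), 4 (307) and 5 (220). For cortex at 15 months it ran from 103 to 139, moved by AD11 replicate 3 (103). For hippocampus at 15 months it ran from 89 to 179, moved by VH replicates 3 (91) and 4 (89). For the interaction in basal forebrain, 6 against 1 month it ran from 0 to 7, moved by AD11 1 month replicates 1 (2) and 4 (7), AD11 6 months replicates 4 (1) and 5 (4), VH 6 months replicate 4 (1). For the interaction in hippocampus, 6 against 1 month it ran from 2 to 106, moved by AD11 1 month replicate 3 (2), VH 1 month replicates 1 (106), 2 (30) and 5 (7), AD11 6 months replicates 2 (35), 3 (6), 4 (29) and 5 (34), VH 6 months replicates 2 (8), 3 (8), 4 (37) and 5 (28). For the interaction in basal forebrain, 15 against 3 months it ran from 0 to 21, moved by AD11 3 months replicate 5 (2), AD11 15 months replicate 1 (2), VH 15 months replicates 3 (21) and 4 (1). For the interaction in cortex, 15 against 3 months it ran from 231 to 1060, moved by AD11 3 months replicate 2 (260), VH 3 months replicates 1 (1060), 3 (231), 4 (336) and 5 (282), AD11 15 months replicate 4 (365), VH 15 months replicate 1 (361). For the interaction in hippocampus, 15 against 6 months it ran from 0 to 1, moved by AD11 6 months replicate 2 (1). For VH basal forebrain, 6 against 1 month it ran from 382 to 798, moved by VH 1 month replicates 1 (561) and 4 (513), VH 6 months replicates 2 (382) and 4 (422). For VH cortex, 6 against 1 month it ran from 139 to 778, moved by VH 1 month replicates 1 (206), 2 (261), 3 (197) and 5 (261), VH 6 months replicates 3 (139) and 5 (778). For VH hippocampus, 6 against 1 month it ran from 1382 to 2408, moved by VH 1 month replicates 2 (1415) and 5 (1382). For VH basal forebrain, 15 against 3 months it ran from 840 to 2236, moved by VH 15 months replicate 1 (840). For VH hippocampus, 15 against 6 months it ran from 565 to 1286, moved by VH 6 months replicate 1 (701), VH 15 months replicates 2 (565) and 4 (646).

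Without AD11 replicate 2 the striatum marker mean in hippocampus at 1 month was -0.036. The ribosomal protein mean in basal forebrain at 3 months was 0.059 without VH replicate 5 and -0.051 without AD11 replicate 5. Without VH basal forebrain replicate 2 at 15 months the reactive astrocyte mean there was 0.019 and the interferon mean over basal forebrain and cortex 0.065.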

Other observations

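The genotype differences of named genes were set against each other in all 66 pairs of the 12 comparisons, which share no arrays. In basal forebrain the differences at 1 and 6 months ran alike (r = 0.503, rho = 0.296, 15983 genes), as did those at 3 and 15 months (r = 0.514, rho = 0.338, 15721 genes), while 1 month ran against 3 months (r = -0.376, rho = -0.285) and 15 months (r = -0.349, rho = -0.328). Within an age, cortex and hippocampus ran alike at 1 month (r = 0.491, rho = 0.419), 6 months (r = 0.415, rho = 0.349) and 15 months (r = 0.465, rho = 0.350), less so at 3 months (r = 0.184, rho = 0.0860). Genes are not independent of each other, so no p is given. The 1-month and 6-month arrays share an array design, as do those of basal forebrain at 3 and 15 months, so the likeness is not free of shared probes. Basal forebrain at 1 and 6 months shared the lower striatum mean (-0.95 and -1.04). The r was not recomputed with this mean as a covariate.

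Over the 12 comparisons and the 4 means over areas, 126 of 608 list tests passed with the preset correlation. With a correlation estimated for each list 0 passed, and 19 passed in fry. The calls, as higher and lower with the range of the list means, were cytosolic ribosomal proteins 3 and 8 (-0.16 to 0.093), interferon-stimulated genes 0 and 10 (-0.36 to 0.042), basal forebrain cholinergic neurons 4 and 3 (-0.94 to 0.66), homeostatic microglia 4 and 3 (-0.18 to 0.16), MHC class I and antigen processing 3 and 4 (-0.16 to 0.22), circadian clock 0 and 6 (-0.20 to 0.094), glutamatergic neurons 2 and 4 (-0.55 to 0.32), hypothalamus 3 and 3 (-0.61 to 0.77), meninges and fibroblasts 2 and 4 (-0.49 to 0.56), cortex 2 and 3 (-0.50 to 0.30), immediate early genes 0 and 5 (-0.38 to 0.20), myelinating oligodendrocytes 5 and 0 (-0.13 to 0.30), striatum 3 and 2 (-1.04 to 0.75), astrocytes 2 and 2 (-0.19 to 0.16), endothelium and pericytes 1 and 3 (-0.22 to 0.15), reactive astrocytes 0 and 4 (-0.23 to 0.084), synaptic vesicle and release 2 and 2 (-0.20 to 0.14), thalamus 2 and 2 (-0.32 to 0.48), ependymal and ciliated cells 1 and 2 (-0.31 to 0.23), GABAergic neurons 3 and 0 (-0.18 to 0.32), oxidative phosphorylation 3 and 0 (-0.033 to 0.086), choroid plexus 0 and 2 (-0.72 to 0.25), heat shock and unfolded protein response 0 and 2 (-0.17 to 0.026), hippocampus 1 and 1 (-0.33 to 0.21), postsynaptic density 0 and 2 (-0.21 to 0.086), amyloid precursor processing and tau 1 and 0 (-0.073 to 0.095), complement 0 and 1 (-0.15 to 0.19) and Wnt signalling 1 and 0 (-0.13 to 0.10).

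Camera made no call for the following lists, with the range of the means and the lowest adjusted p: cholinergic receptors (-0.13 to 0.13, 0.0704), cytokines and chemokines (-0.086 to 0.086, 0.0831), disease-associated microglia (-0.082 to 0.12, 0.0554), glucocorticoid response (-0.16 to 0.089, 0.0704), immunoglobulin and transgene (-0.088 to 0.15, 0.181), MHC class II (-0.14 to 0.15, 0.201), NGF and neurotrophin signalling (-0.11 to 0.040, 0.0680), oligodendrocyte precursors (-0.091 to 0.13, 0.0704), red blood cells (-0.20 to 0.35, 0.230) and T and B lymphocytes (-0.10 to 0.11, 0.113). Fry called cholinergic receptors lower in 3 of the comparisons and NGF and neurotrophin signalling lower in 1. The check of sex-linked genes held 1 measured gene and was not tested.

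Choroid plexus genes had a lower mean in cortex at 6 months (0 up, 0 down and 21 not passing of 21, 0 up and 0 down when adjusted over the list alone, mean -0.72, set test adjusted p = 0.000760, adjusted p = 0.717 with an estimated correlation). Tissue carried over may account for this, and in hippocampus at 15 months the choroid plexus mean was 1.97 with the slide as a fixed block against -0.46 without it.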
